A study of Mus musculus with 19 samples.

How the data were processed

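The study measured where SPEN sits on chromatin in cells of the adult mouse testis (FVB/N strain) by chromatin immunoprecipitation followed by sequencing (ChIP-seq). There were 19 libraries. In mixed testicular cells, 3 libraries used an antibody against the N-terminal part of SPEN and 9 an antibody against an internal part of the protein. In a population enriched in spermatocytes (up to 80%, per the labels' protocols), 4 libraries used the internal antibody. The remaining 3 were background libraries, namely an IgG precipitation and an input from testicular cells and an input from spermatocytes. Per the labels, chromatin was sheared to 100 to 500 bp, and each library combined 5 to 6 precipitations before sequencing. Each condition therefore had 1 library, the spread between precipitations was lost by the pooling, and nothing in the files measures it.

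Per the submitters' processing notes, the tools were Bowtie2, SAMtools and HOMER and the genome build was mm10; their versions were not given in the sources used here. The deposited data are a peak list and an annotated copy of it for each library, and all positions, widths and scores were the same in both copies. Peaks were called in each library separately by a program whose peak names carry MACS, per the file headers and peak names, and HOMER annotated them on mm10, per the file headers. The version of the peak caller, its threshold and the control it was given were not given in the sources used here. The peak score is the authors' value from their peak caller, per the file headers. Its lowest value lay between 50.0 and 50.02 in every list. The score was used to rank or filter peaks, and its median was compared between lists only at positions called in every library. The distance to the nearest transcription start site (TSS) in bp and the gene assigned to each peak are the authors' deposited HOMER annotation. Folder names in the file headers split the libraries into a set of 16 and a set of 3, and the set of 3 held exactly the N-terminal antibody libraries. If the folders mark processing runs, which the headers do not state, antibody and run cannot be told apart. No background library was in the folder of the N-terminal libraries.

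Sequencing depth is unknown, because the files hold peaks and no read totals. A longer list can come from more reads as well as from more binding, and no interval below covers that. The highest share of identical peak intervals between any pair of libraries was 0.187% of the shorter list, so no pair of lists was a copy of the same library.

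Groups were taken from the labels, and the definitions in this paragraph were fixed before the data were examined. Peaks were shared when they had at least 1 bp in common. A peak at background was one that shared a base with any peak of the IgG or of either input, and the remaining peaks of a SPEN library were called antibody-specific. For IgG and input, the same quantity was computed against the other 2 background libraries. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Each list of overlaps was set against a chance level, the mean over 1000 random circular shifts of the peaks along each chromosome. Chromosome lengths were taken as the largest peak end in any list. Loci were made by merging antibody-specific peaks of the 16 SPEN libraries that shared a base, with 200 shifted sets for chance. With 1 library per condition no single condition could be tested against another, and libraries of other times or temperatures were not treated as replicates: every statement compares these libraries, not the conditions.

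A gene held a peak when an antibody-specific peak was assigned to it within 5 kb of its TSS. The 13 gene lists covered heat shock proteins and co-chaperones; apoptosis and the p53 pathway; the Notch pathway; SPEN with corepressors and nuclear receptors; the X inactivation locus; spermatogonia; meiotic prophase; spermatids; Sertoli cells; Leydig, peritubular and blood cells; sex-linked testis genes; constitutive promoters; and abundant non-coding RNA genes. They held 282 genes, of which 279 were matched to the NCBI RefSeq gene table of GRCm38.p6, the same assembly as mm10; Ube1y1 and Uba1y are the same gene there, which leaves 278 genes. The number of members with a peak was ranked among 10000 random lists of the same size and the same number of protein-coding genes, drawn from 26220 genes. The lists and the size of the random lists were fixed before the data were examined; drawing by protein-coding class was added afterwards. The percentile counts ties at their midpoint. Repeat classes had been fixed as well, whereas the L1Md and IAP families were picked after the data were seen.

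Loci named in the text followed a fixed rule. For each antibody, temperature and cell population they are up to 10 loci with a peak in the most heat-shocked libraries and not the untreated one, up to 10 of the untreated library alone, and, between antibodies and between populations, up to 10 present on both sides. Ties were ordered by the highest score, and a locus took the name of a gene whose TSS lay within 10 kb. Every list gene with a peak in at least 2 SPEN libraries was named, and Spen, Hspa1a, Hspa1b, Hsph1 and Xist were always reported. The text gives a selection of these loci, and list genes with 1 peak were named as examples after their values were seen. Motif content had been planned but needs a genome sequence, which was not used here.

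Alternatives tried were peaks above the median score of their list, an overlap of at least 50% of both peaks, peak centres within 1 kb, no background removal, background from the inputs alone, the 1000 highest-scoring peaks, uniform random positions for chance, windows of 1 kb and 50 kb around the TSS, and leaving out the library with the most peaks. Overlap code was tested on simulated data: with 60% of 751 peaks implanted in a second list, 60.1% were recovered, and with none implanted 0.666% were. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.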

Results

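SPEN is a large RNA-binding protein that recruits corepressors, known from Notch signalling and from X inactivation. To ask where it sits on chromatin in male germ cells and how heat shock affects this, cells were kept at 32 °C, the temperature of the testis, or brought to 38 °C or 43 °C for 15 or 30 min, with recovery for 2 or 4 h in some samples. The internal antibody covered the untreated state and 8 heat-shocked states in testicular cells, and the untreated state and 3 states at 43 °C in spermatocytes. The N-terminal antibody covered the untreated state and 2 states at 38 °C. Lists held 1641 to 29315 peaks, and each condition had 1 library, so values have no replicate error.

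Most SPEN lists resembled the background lists. In 14 of the 16 SPEN libraries between 59.8% and 80.2% of peaks lay at positions also called in IgG or input, against a chance level of at most 2.82%. The background libraries overlapped each other to a like degree, with 71.3% of IgG peaks (interval 69.4 to 73.1%), 58.5% of testicular input peaks (56.7 to 60.3%) and 71.0% of spermatocyte input peaks (68.7 to 73.2%) called in another background library. Peaks outside the other background lists numbered 662 in IgG, 1214 in testicular input and 476 in spermatocyte input. The 14 SPEN libraries held 333 to 1442 antibody-specific peaks, judged against all 3 background lists. Numbers of this size thus also arise without a SPEN antibody, and the term antibody-specific does not by itself mean SPEN binding. The other 2 SPEN lists stood apart. Untreated testicular cells with the internal antibody had 29315 peaks with 6.63% at background (6.35 to 6.93%), and spermatocytes at 4 h of recovery from 43 °C had 9707 peaks with 15.9% at background (15.2 to 16.6%).

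**Figure D1:**
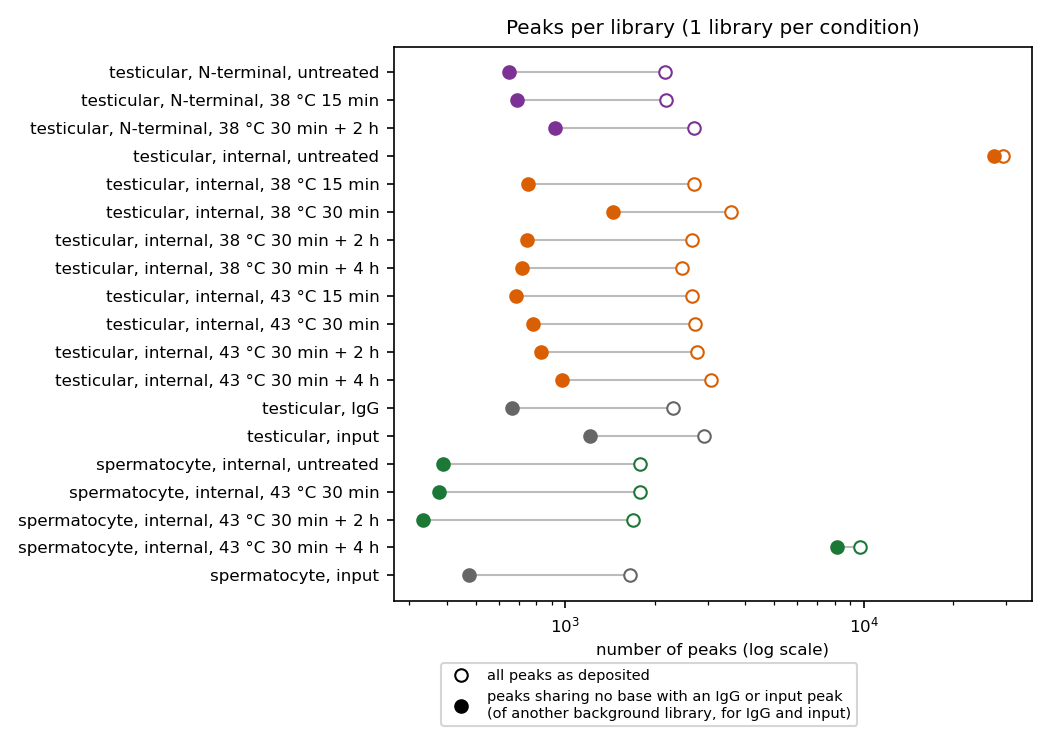
Number of peaks per library on a log axis, with open circles for all deposited peaks and filled circles for peaks sharing no base with a background peak; each row is 1 library. The untreated testicular library of the internal antibody (29315 peaks, 27370 antibody-specific) and the spermatocyte library with 4 h recovery (9707 and 8164) lie to the right of the others.

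With the internal antibody in testicular cells, the untreated library held 27370 antibody-specific peaks and the 8 heat-shocked libraries 683 to 1442, a ratio of 35.8 to the median of 764 peaks. Lists were short at 15 min, with 751 peaks at 38 °C and 683 at 43 °C, and at 4 h of recovery, with 717 and 971 peaks. Of the peaks of the heat-shocked libraries, 11.8% to 18.4% lay in the untreated list in 7 libraries. The library at 38 °C for 30 min without recovery differed, with 688 of its 1442 peaks in the untreated list (47.7%, interval 45.1 to 50.3%). Chance levels were 0.354% to 0.742%. The ratio was 10.8 with background peaks kept and 64.2 without the Y chromosome, a choice made after seeing the data, which also gave a median share in the untreated list of 19.6%; with the 1000 highest-scoring peaks of each library that share was 3.37%.

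The next loci were in the untreated testicular library and lacking in all its heat-shocked libraries of 38 °C or in all of 43 °C. The top locus absent from all 43 °C libraries was a promoter peak of Gm13238 on chromosome 4 (145836428 to 145837698, score 1001, -156 bp from the TSS), a locus held by 5 of the 16 SPEN libraries. Gm13139 in the same region had a promoter peak (145780963 to 145781979, score 472) and an upstream peak (145774194 to 145775342, score 594), and Gm13152 an intronic one (147181316 to 147181967, score 464). On chromosome 8, peaks lay near 4930467E23Rik (19723336 to 19725564, score 687) and in an intron of 2610005L07Rik (20423954 to 20425270, score 482). An intronic L1Md_T element on chromosome 16 (16507246 to 16508395, score 646) was absent from every heat-shocked testicular library of this antibody.

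Some loci were held by heat-shocked testicular libraries of the internal antibody and not by its untreated library. At 38 °C, 18 loci were in all 4 libraries and not in the untreated one, 10 of them on the Y; at 43 °C there were 39, with 29 on the Y. Of all antibody-specific peaks in these 8 libraries 17.1% to 48.5% were on the Y, as were 36.1% in IgG and 29.7% in testicular input. At 38 °C the highest-scoring of them was an intronic site on chromosome 14 (21312538 to 21313126, score 173), which was found in 9 SPEN libraries including both heat-shocked N-terminal ones. Named genes next to such loci at 43 °C were Olfr1459, an olfactory receptor gene (chromosome 19, 13140643 to 13140944, score 146), and the Y-linked Gm20826 (7629703 to 7630005, score 139) and Gm20815 (8840652 to 8840854, score 130). A site on the Y at 4154037 to 4154667 in a SYNREP_MM repeat was among the 10 named at both temperatures and was held by 11 SPEN libraries.

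The temperatures gave partly shared lists at matched times. Of the 38 °C peaks, 18.5% (15.8 to 21.5%) were in the 43 °C list at 15 min, 25.7% (22.6 to 29.0%) at 2 h of recovery and 26.2% (23.0 to 29.6%) at 4 h. At 30 min without recovery the share was 8.11% (6.76 to 9.64%) of the longer 38 °C list, and 14.9% (12.5 to 17.6%) of the 43 °C peaks lay in it. Over all 28 pairs of heat-shocked testicular libraries of this antibody the median share was 22.2%. Leaving out the Y chromosome, the matched pairs had a median of 15.1%.

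With the N-terminal antibody, the heat-shocked libraries held more antibody-specific peaks than the untreated one. There were 648 peaks in untreated cells, 690 after 15 min at 38 °C and 926 at 2 h of recovery from 30 min, or 1.06 and 1.43 times the untreated number. Of these, 26.1% (22.8 to 29.5%) and 22.0% (19.4 to 24.8%) lay in the untreated list. The untreated library and both heat-shocked ones had 97 loci in common. Loci in both heat-shocked libraries and not the untreated one numbered 100, of which 41 were on the Y, where 35.2% and 41.0% of all antibody-specific peaks of these libraries lay. Among them were a B1_Mus2 repeat upstream of Sema3f, a secreted semaphorin gene (chromosome 9, 107719836 to 107720045, score 152), and a site near the microRNA gene Mir6340 (chromosome 2, 173707521 to 173707975, score 129). The strongest locus of the untreated list alone was intergenic on the Y (5954330 to 5954612, score 154).

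Sites called with both antibodies in the same state were a minority of each list. The internal list held 31.5% of N-terminal peaks in untreated cells (27.9 to 35.2%), 21.2% after 15 min at 38 °C (18.2 to 24.4%) and 13.7% at 2 h of recovery (11.6 to 16.1%), against chance levels of at most 0.427%. The untreated internal list is far longer than the others, and its share was 73.8 times chance, against 265 and 296 times in the other states. Even full sharing gives a lower fold where the chance level is higher, so these folds are not comparable between states. In the reverse direction, 0.756% of the untreated internal peaks lay in the N-terminal list, against 17.1% and 19.3% in the other states. Only 7 loci were shared by the antibodies in all 3 states, led by an MMERGLN-int retroviral sequence on chromosome 12 (20229811 to 20234473, score 468) and an L1Md_T element on chromosome 14 (19094530 to 19095019, score 236). When each list was limited to its 1000 highest-scoring peaks, only the untreated internal list was shortened, so only the untreated pair could change. The median share went from 21.2% to 13.7%, which is the unchanged share at 2 h of recovery. Antibody and header folder went together in these files.

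In enriched spermatocytes, the untreated library held 389 antibody-specific peaks, the 43 °C library 378, the one with 2 h of recovery 333 and the one with 4 h of recovery 8164. The ratio of the untreated library to the heat-shocked median was 1.03. The untreated list held 16.9% (13.3 to 21.1%) of peaks at 30 min and 13.5% (10.0 to 17.7%) at 2 h of recovery. At 4 h of recovery 1.32% of the peaks (1.09 to 1.59%) were in the untreated list, while 25.7% of untreated peaks (21.4 to 30.4%) were in the long list. The untreated and all 3 heat-shocked libraries had 16 loci in common. Only 25 loci were in all 3 heat-shocked libraries and not in the untreated one. They were led by an intronic site on chromosome 1 (63629818 to 63630711, score 521). Next came intergenic sites on chromosome 8 (20099695 to 20101153, score 371) and chromosome 1 (171514971 to 171515894, score 362). Also included was an L1_Mus4 element near Mup8, a major urinary protein gene (chromosome 4, 60216660 to 60216943, score 164).

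Spermatocyte peaks were found in the testicular list of the same state at 28.0% in untreated cells (23.6 to 32.8%), 9.52% at 30 min of 43 °C (6.76 to 12.9%), 10.8% at 2 h of recovery (7.69 to 14.7%) and 0.882% at 4 h (0.691 to 1.11%). Chance levels were 1.08%, 0.0471%, 0.0730% and 0.0166%. The last share is low because the spermatocyte list is long: of the testicular peaks, 0.413%, 4.63%, 4.35% and 7.52% (5.94 to 9.36%) were in the spermatocyte list in the same order. A single locus, an L1Md_F3 element on chromosome 9 (11620099 to 11620298, score 132), was shared in all 4 states. An intergenic site near Rn4.5s, a small RNA gene, on chromosome 6 (47739615 to 47741006, score 296) was shared in 2 states.

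**Figure D2:**
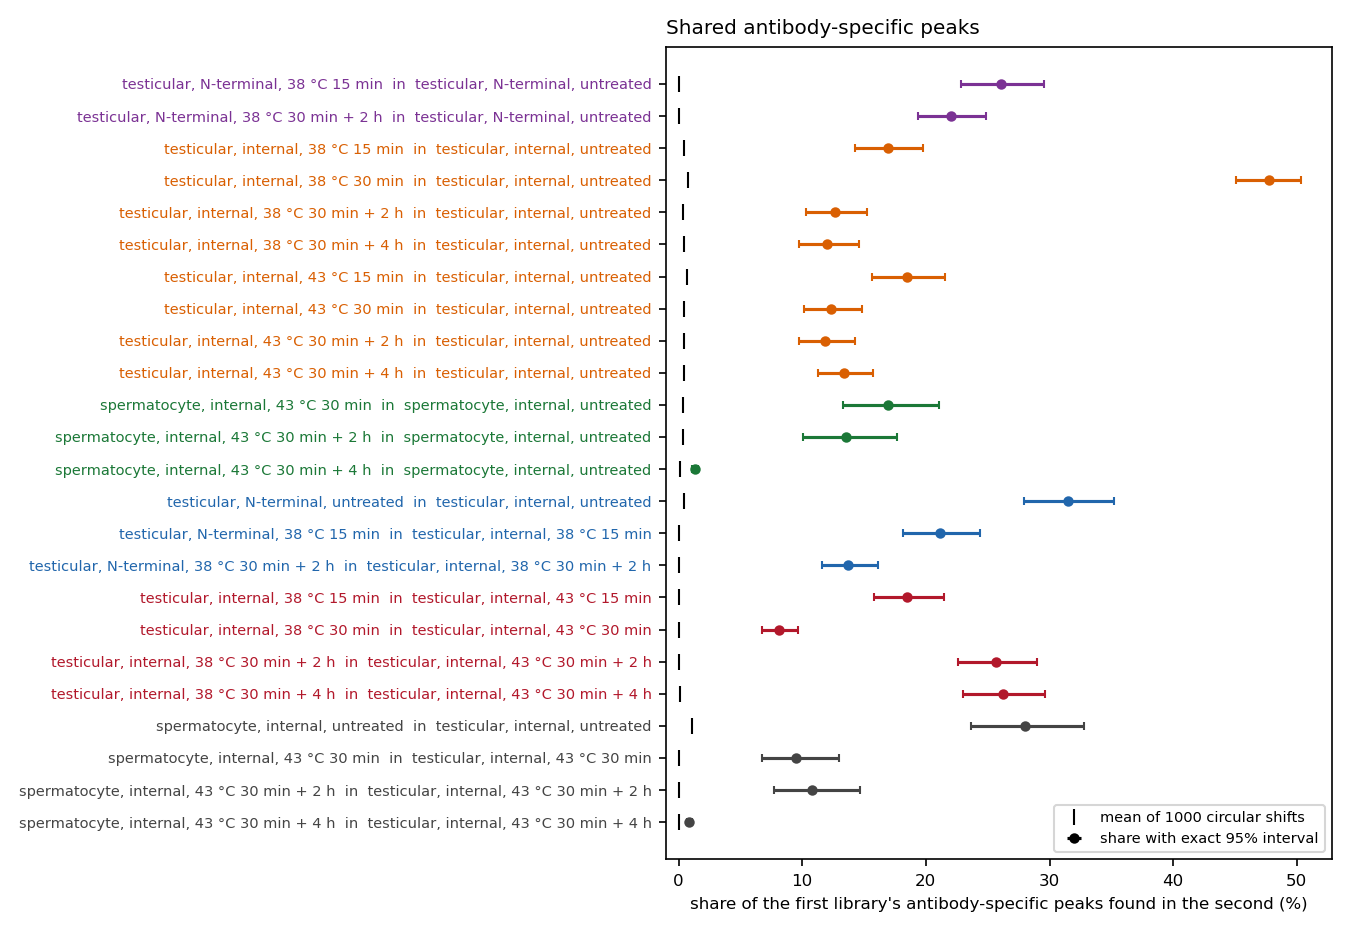
Share in percent of the antibody-specific peaks of 1 library found in another, with exact 95% intervals as bars and the mean of 1000 circular shifts as a black tick; colours mark the comparison families. Every point lies above its tick, and the 38 °C 30 min library of the internal antibody (47.7%) lies above the other heat-shocked libraries.

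Across all 16 SPEN libraries, antibody-specific peaks merged into 36873 loci, of which 31888 were seen in 1 library. Those in at least 3 libraries numbered 1615, against 6.22 in the average shifted set, and 95 were in at least 8; no locus was in all 16. Of the 1615, 30.2% lay on the Y chromosome (28.0 to 32.5%), 23.8% in LINE elements (21.8 to 26.0%), 17.7% in LTR elements (15.9 to 19.7%) and 1.11% at promoters (0.662 to 1.76%). Leaving out the 2 longest lists, a choice made after seeing the data, left 1028.

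Genes with a peak within 5 kb of the TSS numbered 4630 in untreated testicular cells with the internal antibody, 826 in spermatocytes at 4 h of recovery and 111 in testicular cells after 30 min at 38 °C. The other 13 SPEN libraries had 25 to 45. Spen itself had 1 peak, 491 bp from its TSS in an intron on chromosome 4 (141537949 to 141538263, score 53.4), and only in untreated testicular cells. Hspa1b, a heat-inducible Hsp70 gene, had 2 peaks in the same library alone, the higher in its exon on chromosome 17 (34957942 to 34958205, score 72.4). Hsph1, a heat shock protein gene, had a gene-body peak (score 75.3) in spermatocytes at 4 h of recovery and no peak within 5 kb of its TSS. Neither Hspa1a nor Xist, the RNA gene of X inactivation that SPEN acts with, had a peak in any library.

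In untreated testicular cells, 43 of the 278 list genes had a peak, where random lists averaged 53.6 (percentile 5.24). Of 24 genes of SPEN, corepressors and nuclear receptors 8 had one (random mean 4.86, percentile 93.5), among them the corepressor gene Ncor1 (score 149), Tbl1xr1 (71.2) and the glucocorticoid receptor gene Nr3c1 (64.2). Heat shock proteins and co-chaperones gave 8 of 30 (6.06, percentile 80.6), including Hspa4 (144), Hspe1 (132) and the heat shock factor gene Hsf5 (133). Meiotic prophase genes gave 7 of 34 (6.88, percentile 53.5), including Ddx4 (216), Sycp1 (162), which encodes a synaptonemal complex protein, and Sycp3 (94.2). The Notch pathway gave 5 of 22 (4.46, percentile 62.2), among them Numb (90.0) and Hey2 (69.1). Spermatogonia markers gave 4 of 16 (3.24, percentile 68.6), led by Dazl (194), and constitutive promoters 4 of 20 (4.06, percentile 50.8).

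Lists with few peaks in that library were spermatid genes with 2 of 28 (random mean 5.67, percentile 3.58), apoptosis and p53 genes with 1 of 20, Bcl2 (4.06, percentile 3.71), and Leydig, peritubular and blood cell markers with 0 of 20 (4.06, percentile 0.5). Sertoli cell markers gave 2 of 17 (3.46, percentile 20.6), sex-linked testis genes 2 of 23 (4.66, percentile 8.39), non-coding RNA genes 0 of 16 (1.14, percentile 15.4) and the X inactivation locus 0 of 8 (1.11, percentile 14.8). Spermatocytes at 4 h of recovery had peaks at 8 list genes (9.33, percentile 34.6), among them Sycp1, Tex12, Pparg and Eef1a1. Sycp1, the translation factor gene Eef1a1 and the Y-linked Ssty1 were the list genes with a peak in at least 2 libraries. Sycp1 and Eef1a1 had theirs in the 2 longest lists; for Sycp1 the peaks on chromosome 3 were 102935533 to 102935837 and 102935518 to 102935711. Ssty1 is a multicopy gene, and its peaks in 3 heat-shocked testicular libraries lay near another copy than the one in the gene table, so its assignment is uncertain.

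The longest lists were richer in L1Md and IAP elements. LINE elements held 28.4% of antibody-specific peaks in untreated testicular cells (27.9 to 29.0%) and 29.2% in spermatocytes at 4 h of recovery (28.3 to 30.2%), against 20.1% to 27.1% in the other 14 SPEN libraries. LTR elements, at 18.6% and 20.8%, lay within the range of the others (7.20% to 22.7%). The families within these classes were picked after the data were seen and differed more. L1Md elements, a group of mouse LINE-1 subfamilies, held 23.9% (23.4 to 24.4%) and 22.7% (21.8 to 23.6%) in these 2 lists. The other 14 SPEN libraries had 9.96% to 18.6% and the background libraries 10.9% to 12.5%. IAP elements, a family of endogenous retroviruses, made up 9.17% (8.83 to 9.52%) and 10.1% (9.46 to 10.8%) in the 2 long lists, 0.514% to 5.55% in the other SPEN lists and 1.05% to 6.18% in background. Promoters took 6.68% (6.39 to 6.98%) in untreated testicular cells, 2.57% (2.24 to 2.94%) in spermatocytes at 4 h, 0.386% to 1.66% in the other 11 testicular and 1.80% to 3.44% in the other 3 spermatocyte SPEN libraries. After 30 min at 38 °C L1Md elements held 18.6% (16.6 to 20.7%), the highest of the heat-shocked testicular libraries. Lists of different length reach different depths of weak peaks, which these shares do not correct for.

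**Figure D3:**
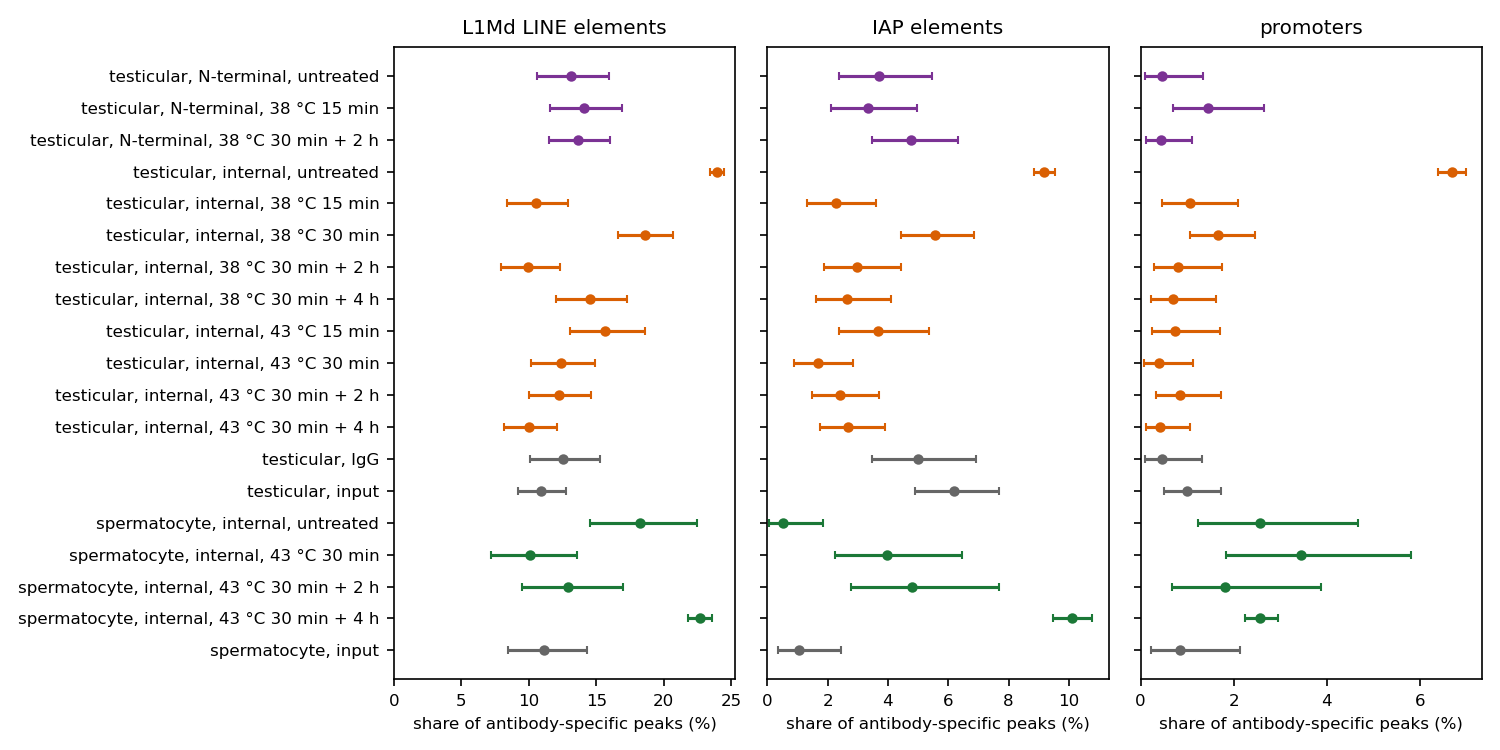
Share in percent of antibody-specific peaks at L1Md LINE elements, IAP elements and promoters in each of the 19 libraries, with exact 95% intervals; colours mark antibody and cell population, and grey marks background libraries. The 2 long lists lie at 23.9% and 22.7% for L1Md elements, above the other libraries.

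The Y chromosome separated the cell populations. In testicular libraries other than the untreated internal one, 20.4% to 32.7% of all peaks lay on the Y, including 24.2% of IgG peaks (22.5 to 26.0%) and 23.2% of input peaks (21.7 to 24.8%). Spermatocyte libraries had 0.721% to 3.66%, with 2.74% in the input (2.01 to 3.65%). Untreated testicular cells with the internal antibody had 2.46% on the Y, but the number of peaks there, 721, was within the testicular range of 558 to 1002. The spermatocyte range was 39 to 70.

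**Figure D4:**
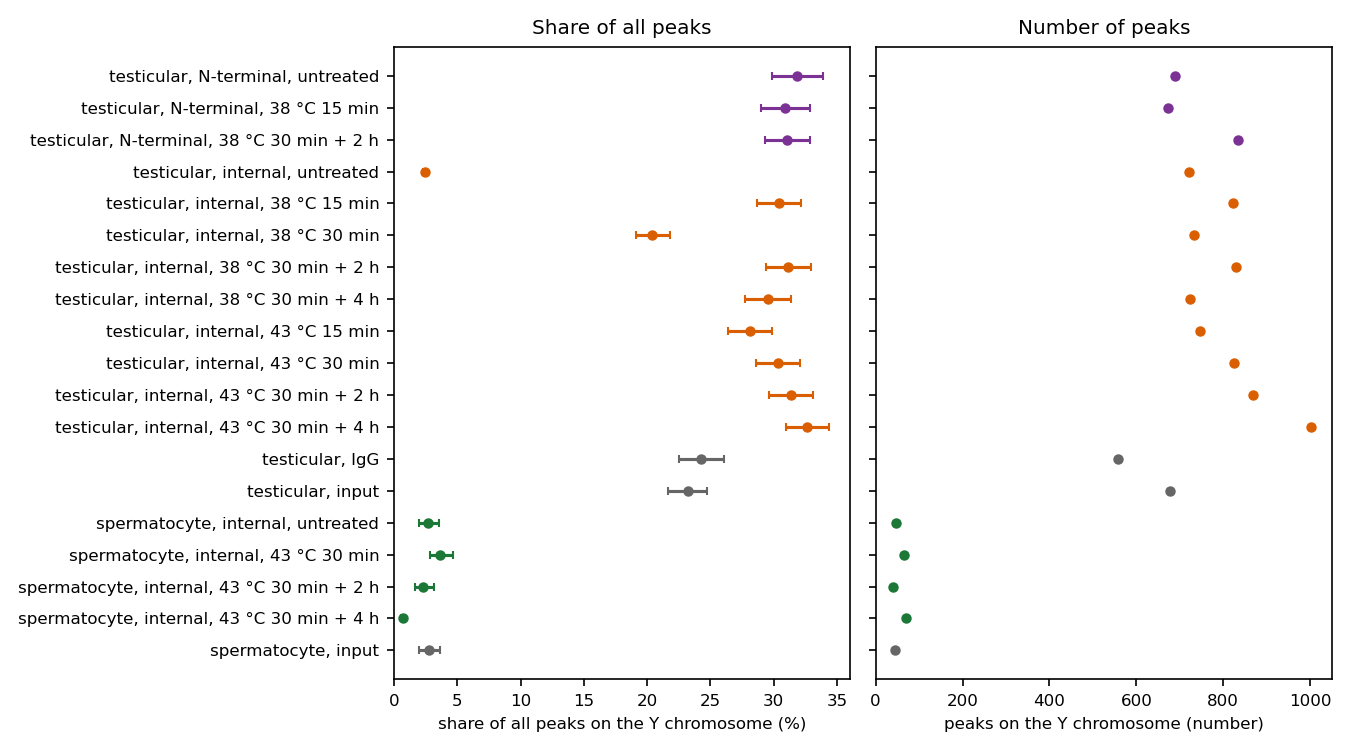
Share of all peaks on the Y chromosome in percent with exact 95% intervals (left) and number of Y peaks (right) in each of the 19 libraries; colours mark antibody and cell population, and grey marks background libraries. Testicular libraries have 558 to 1002 Y peaks and spermatocyte libraries 39 to 70.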

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

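The tests of heat shock across series, of CpG islands, of SPEN on the Y and of the inputs on the Y were chosen after their results were seen, as were the tests at background positions and of the Y share over all libraries. The antibodies differed in their peak numbers under the same heat shock of testicular cells. With the N-terminal antibody, the number of antibody-specific peaks was 1.06 times the untreated number after 15 min at 38 °C and 1.43 times at 2 h of recovery. At 15 min this was 690 against 648 peaks, and 2175 against 2164 before background removal, so the N-terminal list hardly changed there. With the internal antibody the same states gave 0.0274 and 0.0271 times the untreated number. This difference was not tested, since each state had 1 library, and it rests on the long untreated list of the internal antibody.

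The lists of untreated testicular cells and of spermatocytes at 4 h of recovery were many times longer than the others. More reads as the whole cause would also call more background positions, which was not seen. The untreated testicular list held 71.8% of the 1540 positions of IgG and testicular input, and the heat-shocked lists 76.5% to 86.8%. The spermatocyte list held 59.1% of the input positions and the shorter ones 63.2% to 67.1%. Of positions called in only 1 of 2 lists, at most 43.0% (38.7 to 47.4%) and 39.9% (34.6 to 45.4%) were in the long one. The median score at the 460 IgG positions called in every library went the other way, being highest in the 2 long lists (454 and 434). It was 327 to 410 in the heat-shocked testicular lists of the internal antibody and 323 to 360 in the other spermatocyte SPEN lists. More reads could give such scores, so depth as the whole cause is not decided. In the test set beforehand, 23.4% (21.2 to 25.8%, 316 of 1350) of untreated testicular peaks scoring at least 150 were called in any of the 8 heat-shocked libraries (9.41% without 38 °C for 30 min). Of the spermatocyte ones, 28.9% (23.1 to 35.3%, 65 of 225) were called in any of the other 3. Both shares lay below the 50% set for depth. That test cannot decide, because the score may rise with read number. A peak scoring 150 in a deeper library could then fall under the lowest score of a shallower one. Lower numbers of peaks after heat shock in every series are not what the lists hold, since the untreated one was the longest in 1 of 3 series. A preference for GC-rich fragments could not be judged without a genome sequence. CpG islands held 4.71% of the untreated testicular peaks, 1.49% of the spermatocyte peaks and at most 1.87% elsewhere. How well each precipitation worked, SPEN binding that differs between cell states and sequencing depth stay open. Each of these may be the source with 1 library per state.

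The Y chromosome held far more peaks in testicular libraries than in spermatocyte libraries. Binding of SPEN there is argued against as the cause, since the testicular input, with no antibody, had 23.2% of its peaks on the Y. Lower depth of the spermatocyte libraries is argued against by the 500 highest-scoring peaks of each list: 3.80% to 14.4% of them were on the Y in the 14 testicular libraries (median 8.90%) and 1.20% to 3.00% in the 5 spermatocyte libraries. On the inputs alone, the value of the test set beforehand, 6.60% (4.59 to 9.14%), lay above the upper bound for spermatocytes (3.00%, up to 4.90%) as that test required, though its interval reaches below it. A difference between the cell populations cannot be told apart from one between their preparations, since both go with the 2.74% of the spermatocyte input, and either may be the source.

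The 2 long lists shared sites although they came from different populations and states: 2902 of the 8164 spermatocyte peaks (35.5%, 34.5 to 36.6%) were in the untreated testicular list, against 0.577% by chance. Reads shared between near-identical repeat copies could give such sharing. Among peaks whose annotation names no repeat, however, 28.3% of the spermatocyte peaks (26.8 to 29.8%, 948 of 3351) were still shared, where the highest of 200 shifted sets reached 1.19%. The sharing was thus not confined to annotated repeats. Repeats beside a peak and near-identical copies without a repeat annotation, such as duplicated genes, were not covered, so such reads cannot be excluded there. Inside repeats the share was 40.6%. Sites that any efficient library from these cells would show, whatever the antibody, remain a candidate source, and no biological explanation was tested.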

How the results depend on the processing

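No paired analysis was possible because the labels give no replicate numbers and each condition had 1 library; matched states were compared by overlap only. All alternatives fixed before the data were seen were run. Of 115 alternative values of the main results, 63 stayed within the counting interval of the main value (within 1.5 times for counts). Another 51 moved beyond it, 1 passed a threshold and 0 were labelled reversed. Shares and counts have no direction to reverse, so that 0 does not bear on them. The spermatocyte ratio crossed 1, from 1.03 to 0.991 with centres within 1 kb. It counts among the 63 because its main interval (0.891 to 1.19) holds both values. Some of the 63 were identical to the main value, since the limit to the highest-scoring peaks did not shorten the lists behind them. Uniform positions for chance kept all 6 folds over chance within their intervals. For single gene lists, 22 of 39 counts stayed within 1.5 times. Causes were not tested except where the alternative itself removes peaks, and unknown depth limits every count.

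With peaks above the median score of their list, the ratio of untreated to heat-shocked peaks was 0.679 with the N-terminal and 47.4 with the internal antibody in testicular cells, the background share 78.4%, and loci in at least 3 libraries numbered 752. The share of heat-shocked peaks in the untreated list was then 28.2% (N-terminal), 16.3% (internal) and 23.5% (spermatocytes), that between temperatures 29.0% and between populations 17.7%. The median score that set this cut was 64.1 in the untreated internal list and 74.5 to 79.5 in its heat-shocked lists. The ratio of 47.4 thus compares lists cut at unlike scores. Requiring 50% of both peaks gave a ratio of 31.7 for the internal antibody, a background share of 66.1% and a share in the untreated list of 10.4%; with centres within 1 kb these were 44.1, 75.8% and 17.4%. With no background removed the ratio was 10.8, loci numbered 4220, and shares were 58.0%, 46.3% and 64.9% in the untreated list (same order), 55.7% between antibodies, 63.1% between temperatures and 61.7% between populations. Background from the inputs alone gave a ratio of 29.2, a background share of 64.2%, and shares of 28.5% (N-terminal) and 17.4% (spermatocytes) in the untreated list, 27.4% between antibodies and 29.4% between temperatures. The 1000 highest-scoring peaks gave 3.37% in the untreated list for the internal antibody and 13.7% between antibodies. This cut only the lists with more than 1000 antibody-specific peaks, among them the untreated internal one.

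Alternatives chosen after seeing the data were these. Without the Y chromosome the internal ratio was 64.2, its share in the untreated list 19.6%, that between antibodies 15.2% and between temperatures 15.1%. Without the heat-shocked library with the most peaks the N-terminal ratio was 0.939, and without the 2 libraries with the most peaks 1028 loci were left.

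Within 1 kb of the TSS the list genes in untreated testicular cells fell at percentile 0.65 in place of 5.24, and spermatocytes at 4 h of recovery had 4 list genes; within 50 kb the numbers were 98 and 25, at percentiles 29.6 and 2.88 (34.6 at 5 kb for the spermatocytes). In untreated testicular cells, all deposited peaks gave 6.31% at promoters, 22.9% at L1Md elements and 2.46% on the Y, and peaks above the median score 31.1% at L1Md elements and 1.97% on the Y. In spermatocytes at 4 h L1Md shares were 20.2% and 25.6% under these 2 settings. After 30 min at 43 °C in testicular cells they were 9.45% and 4.13%, with 30.3% and 64.5% on the Y. Each list was cut at its own median score, 64.1 in untreated testicular cells and 79.5 in this last library.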

Other observations

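The regions on chromosomes 4 and 8, the zinc finger test without them and the sharing across states below were examined after the data were seen. Spermatocyte lists also shared sites with lists of other states. Of the antibody-specific spermatocyte peaks at 30 min of 43 °C, 45.8% (40.7 to 50.9%) were in the list of untreated testicular cells with the internal antibody, and 33.3% (28.3 to 38.7%) of those at 2 h of recovery. This was 45.5 and 33.2 times chance, against 202 and 148 times in the shorter testicular lists of the same states. A longer list has a higher chance level and so a lower ceiling on the fold, which makes these folds not comparable. In spermatocytes, the list at 4 h of recovery held 43.1% (38.1 to 48.3%) of the peaks at 30 min and 30.9% (26.0 to 36.2%) of those at 2 h. The testicular library at 38 °C for 30 min had 28.2% (25.9 to 30.6%) of its peaks in that same spermatocyte list.

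Promoter peaks at zinc finger genes such as Zfp600 were noticed while looking through the lists, and the hypothesis that zinc finger genes (symbols Zfp and a number) hold peaks within 5 kb of the TSS more often than random genes was formed from them, before their number was known. In untreated testicular cells 90 of 368 such genes had a peak, where random lists averaged 74.0 and had an upper bound of 89 (percentile 98.2). In spermatocytes at 4 h of recovery there were 20, where random lists averaged 12.8 and had an upper bound of 20. Leaving out the 3 Mb around Gm13238 on chromosome 4 and the 2 Mb around 4930467E23Rik on chromosome 8 gave 80 of 353 in untreated testicular cells, at percentile 88.3, and 12 in the spermatocytes, at percentile 48.7. That step was added once the excess was known, and with it the hypothesis stays undecided, since part of the excess rests on those regions. Both regions were also dense in input peaks that no other background library shared, at 26.0 (testicular) and 33.5 times (spermatocyte) the genome-wide density on chromosome 4 and 48.2 and 82.8 times on chromosome 8. In the untreated testicular list the densities were 8.57 and 9.20 times, and in IgG, with 5 peaks in each region, 7.0 and 10.5 times. Reads from gene copies that the reference lacks may contribute to the peaks of Gm13238, Gm13139 and their neighbours, and to the 90 Zfp genes counted above; this was not tested.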
